A study of Pseudomonas putida with 28 samples.

How the data were processed

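RNA of *Pseudomonas putida* mt-2 was measured, per the labels, on custom tiling arrays: total RNA was made into aminoallyl cDNA with actinomycin D present, labelled with Cy3 or Hyper 5 and hybridised with C-runout RNA in the other dye, with the dyes swapped between replicates. The 24 arrays with scanner files formed 6 groups of 4 biological replicates, grouped by sample title. The description of succinate replicate 4 names benzoate instead, and its title was followed. The arrays lay on 3 slides of 8 arrays with 2 groups each, per the file headers.

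Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, which gives each spot's mean intensity and local background in both dyes, without normalization. The log10 ratio of Hyper 5 over Cy3 in the same files, per the file headers, follows spatial detrending, background subtraction, surrogate values and a linear plus lowess dye normalization; it was turned to log2 and to treated over C-runout. The authors also deposited a table of log2 ratios, whose further processing is not given in the sources used here. Its 24 Agilent columns correlate with the log ratios of the scanner files at r = 0.89 to 0.957, with slopes of 0.572 to 0.927. Its 4 GenePix columns of m-xylene correlate at -0.697 to -0.511 with the same replicates and were used only as an alternative, in both directions.

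Spots carrying an outlier mark in the files were left out after background correction. Intensities were background-corrected with normexp (offset 50) and normalised within each array by loess over all non-control probes in limma 3.58.1 under R 4.3.3, then turned to treated over C-runout, and spots of the same probe were averaged. An early run left the marked spots out of the normexp fit as well. It was replaced by the fit on all spots after counts had been seen, because the first choice had itself been made after counts were seen, and it is given as an added alternative.

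The depth was taken as the number of spots well above background per channel, from 750 to 13825 of 14704. No filter on dim probes was applied, and 13580 of 13593 probes could be tested. ORFs were predicted with prodigal 2.6.3 from the tiled sequence, and 77 were found in 9 tiles. The files name no genes, so ORFs carry no gene names. Equal coding length and order to named genes is stated from the gene table of assembly ASM41267v1, without its coordinates. Lists fixed for solvent efflux, stress, catabolite control, sigma factors, central metabolism, ribosome and transposition genes had no match by name and were left out.

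A linear model with the 6 groups and a dye coefficient was fitted per probe with limma, with moderated tests and Benjamini-Hochberg adjustment over all probes of a contrast, at an adjusted p threshold of 0.05. There were 14 contrasts: 6 against C-runout, 5 against succinate and 3 between groups. The ORF means were fitted in the same way. The 6 lists were tested with fry over the 5037 probes without a missing value, adjusted over 84 tests. These were 183 of 705 upper block, 346 of 1098 lower block, 98 of 266 regulator, 910 of 1043 benR tile, 91 of 320 catA1 tile and 356 of 988 pca tile probes, whereas list means cover all probes, so that mean and test can point in different directions. For the regulators in o-xylene the Agilent mean was 0.29 and the test direction downward. That test asks whether a list moves on balance in 1 direction and does not compare it with other genes. Position trends were least squares slopes over the sense probes of a block, compared with succinate by 2-sided exact permutation tests adjusted over 10 tests. Named genes followed a rule fixed before the data were examined: every measured member of the 6 lists, and per contrast the 5 highest and 5 lowest probes outside them that were called with the same sign on every array or without overlap between groups. Probes without signal above background in a partner were not printed.

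The same code was tested on simulated data. For m-xylene against succinate, 35% of probes changed by log2 1 and 81% of those changed by log2 2 were called, and 3.33% of the called probes were unchanged ones (5037 probes). Test values differed from those of limma by at most 6.11e-16. A slope of -0.25 per kb came out as -0.253 (500 probes). Raising the 1804 block probes of all 24 arrays by log2 4 gave block means of 0.81 to 4.14 after loess and 3.03 to 5.32 after median centring. Loess lost over 1 on 12 arrays, and at log2 6 on 18, against 2 for median centring. Median centring overstated log2 4 only on replicates 2 and 4 of m-xylene and succinate (4.93 to 5.32).

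Alternatives were the Agilent log ratio, no background correction, median centring, a dim-probe filter, the median over probes, no dye coefficient, a replicate block, only the groups compared, a minimum of 2-fold, the value table, the GenePix columns and each replicate left out. For the trends they were well-measured probes and the Theil-Sen slope. Figures and tables were made with Python 3.11.15.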

Results

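RNA of *Pseudomonas putida* mt-2, a soil bacterium whose TOL plasmid pWW0 carries the genes for growth on toluene and m-xylene, was measured on custom 2-colour Agilent tiling arrays. Exponential cultures in succinate medium at 30 °C, started from a 100-fold diluted preculture, were exposed for 2 h to vapour of m-xylene, toluene or o-xylene, given 3-methylbenzoate (3MBz, the acid formed from m-xylene by the TOL upper pathway) or benzoate at 5 mM, or left without a further substrate (succinate group). Each of the 6 groups held 4 biological replicates, and each replicate was hybridised on 1 array against RNA of cells kept for 96 h in succinate medium, which the labels call C-runout. Replicates 1 and 3 carried the treated RNA in Cy3 and replicates 2 and 4 in Hyper 5. The labels leave open whether the C-runout RNA came from 1 culture, so a ratio against C-runout, tested against 0, leaves out that control's own spread. Of 14704 spots per array, the number well above background ran from 2823 (succinate replicate 3) to 13825 (3MBz replicate 3) in the treated channel and from 750 (m-xylene replicate 4) to 11548 (toluene replicate 4) in the C-runout channel. The number of arrays limits the precision of every value.

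The arrays tiled 73970 nt in 9 regions with 60-nt probes every 10 nt: 36850 nt of the TOL plasmid and chromosomal regions named after benR, catA1, fcs, pcaG, pcaI, pcaR, pobA and rpoN. The genome build was not given in the sources used here, so positions count from 1 at the start of each tile, and the 77 open reading frames (ORFs) were predicted from the tiled sequence and are called by tile and number. Of 13593 probes, 6406 lay in the sense of an ORF, 5363 antisense and 1824 between ORFs, and the benR tile held probes of 1 strand only. TOL ORFs 31 to 36 (26374 to 34060, minus strand) form the upper block, with zinc alcohol dehydrogenase motifs in ORFs 32 and 36 and an aldehyde dehydrogenase motif in ORF 35. TOL ORFs 3 to 16 (3934 to 15308, minus strand) form the lower block, with a Rieske iron-sulphur motif in ORF 16, an extradiol dioxygenase motif in ORF 11 and an aldehyde dehydrogenase motif in ORF 10. On this plasmid the upper pathway oxidises toluene and m-xylene to carboxylic acids and the lower pathway cleaves the ring of those acids. The regulator pair is TOL ORF 1 (637 to 2337, minus strand, sigma-54 interaction domain) and TOL ORF 2 (2784 to 3749, plus strand, AraC family).

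Values are log2 ratios of treated over C-runout RNA, given as mean ± SD of 4 arrays or with the standard error (SE) of the limma fit, and ORFs, lists and probes were called by limma at an adjusted p under 0.05. Loess normalization was fixed as the main treatment before the data were examined, but the block probes made up 77.8% of probes of their brightness on the m-xylene arrays, 72.9% on the toluene arrays and 51.4% on the o-xylene arrays, and the loess curve took 5.91, 4.28 and 4.47 off the upper block and 6.65, 5.81 and 2.81 off the lower block. Each block value is therefore given after loess, after centring each array on its median without loess, and as the log ratio of the scanner software, in this order and in these words: loess, median-centred and Agilent. Only what passed in the loess values is said to have risen or fallen. After the counts of a list, the parentheses give the counts adjusted over the list alone and then, after the list mean where one is given, the adjusted p of its list test after loess, and "then" introduces the median-centred and Agilent values. Between these scalings the median of all probes moved from 0 to -0.15 (median-centred) and 0.2 (Agilent) in m-xylene, from -0.06 to -0.11 and 0.12 in succinate and from -0.03 to -0.22 and 0.03 in benzoate, and by under 0.1 in the other groups.

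**Figure D1:**
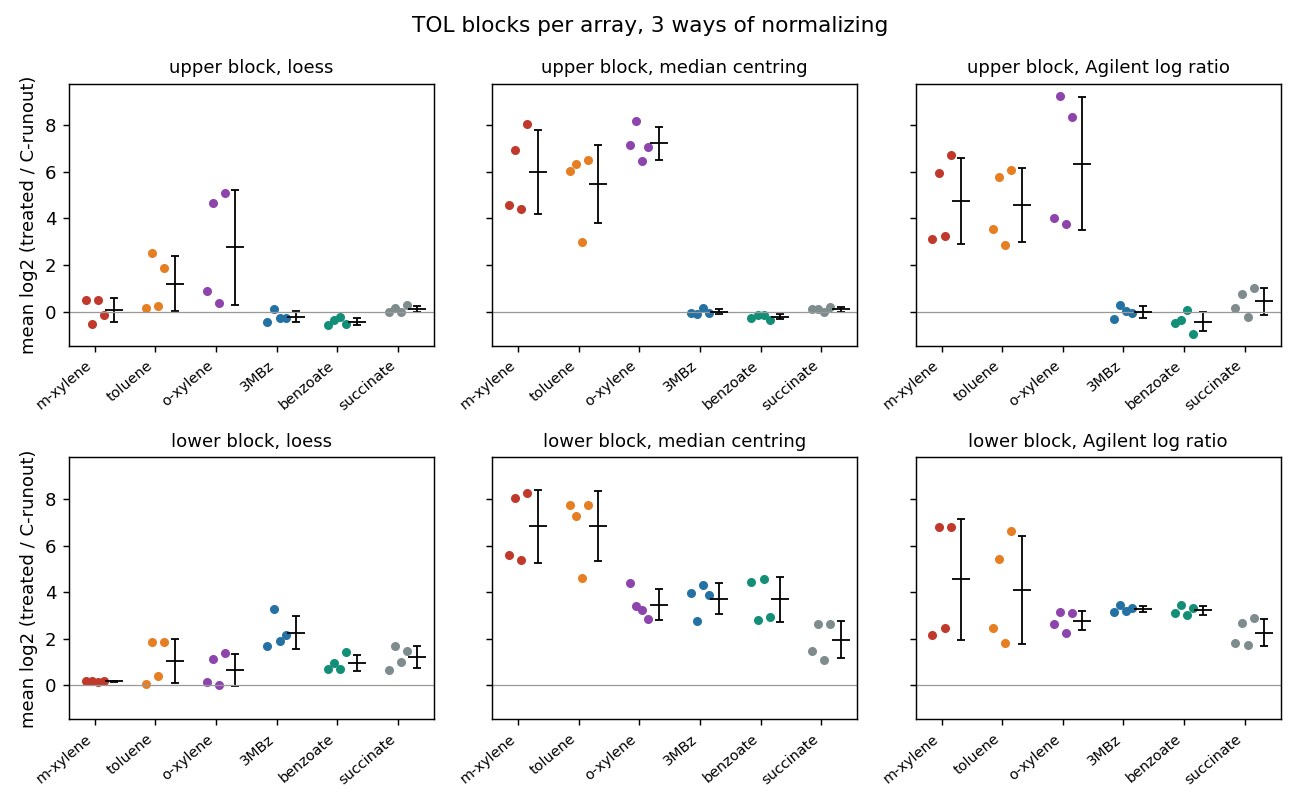
Mean log2 ratio of treated over C-runout RNA over the sense probes of the upper block and the lower block (vertical axis) in each of the 24 arrays (points), with the mean and SD of the 4 arrays of each group (horizontal axis), after loess, median centring and as the Agilent log ratio. The upper block in m-xylene lies at 0.09 after loess and at 6.00 and 4.76 under the other scalings, and the sign of m-xylene against succinate turns between them in both blocks.

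m-Xylene against C-runout asked which of the tiled regions responded to the main substrate of the TOL pathway. The upper block stood at 0.09 ± 0.51 (loess), 6.00 ± 1.80 (median-centred) and 4.76 ± 1.86 (Agilent), and the lower block at 0.17 ± 0.03, 6.82 ± 1.55 and 4.56 ± 2.59. Upper block net signals averaged 36538 in the treated channel against 58 in the C-runout channel with the treated RNA in Cy3, and 20498 against 2564 in Hyper 5, with 100% and 1.8% of the probes well above background in the last pair. No block ORF was called after loess, whereas all 6 upper and 14 lower ORFs were called higher under both other scalings. TOL ORF 1 fell after loess (-4.62, SE 0.56, adjusted p = 2.8e-06) and was lower in the Agilent values (-2.04) but not in the median-centred ones (0.89). TOL ORF 2 stood at -0.36 (SE 0.30, adjusted p = 0.52), 4.90 and 3.45. benR ORF 4, a Rieske ORF with the coding length and order of benA in the gene table of a related *P. putida* strain, where benA belongs to the benzoate dioxygenase genes, stood at 0.34 (SE 0.24, adjusted p = 0.44), 2.81 and 2.74.

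After loess, 831 of 13580 probes were called in m-xylene against C-runout, 32 higher and 799 lower, with 1991 at an unadjusted p under 0.05. The split was 3537 higher and 1671 lower of 5208 after median centring and 3401 higher and 1084 lower of 4485 in the Agilent values. Without m-xylene replicate 1 or 3 the count was 516 or 524. Over the lists, 0 upper block probes were higher and 26 lower of 705 by limma (0 and 23 adjusted over the list alone), 2 lower block probes were higher and 16 lower of 1098 (0 and 10), and 0 regulator probes were higher and 162 lower of 266 (0 and 192). The shift of the list passed the fry test of limma for the regulators (downward, adjusted p = 5.7e-05), which turned upward after median centring (adjusted p = 0.00032) and was not called in the Agilent values (0.36). It was not called for the upper block (0.83; 8.9e-09 median-centred; 1.1e-06 Agilent) or the lower block (0.49, then 1.1e-08 and 6.6e-07). TOL-16941, a probe of TOL ORF 18 (16941 to 17000), fell by 15.09 after loess, and rpoN-1871 of rpoN ORF 4 fell by 11.39, but they stood at -0.92 and 1.87 after median centring and at -5.79 and -3.05 in the Agilent values.

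Toluene against C-runout made the same comparison for the substrate that lacks 1 methyl group of m-xylene. The lower block rose, at 1.04 ± 0.95 (loess), 6.85 ± 1.5 (median-centred) and 4.09 ± 2.31 (Agilent), with all 14 ORFs called under each scaling. The extradiol dioxygenase ORF, TOL ORF 11, rose by 1.55 (SE 0.29, adjusted p = 0.00032), 7.76 and 4.96. In the upper block, at 1.20 ± 1.18, 5.47 ± 1.67 and 4.58 ± 1.61, ORFs 32, 33 and 34 rose after loess (1.51, 1.28 and 1.72) and all 6 were called under the other scalings. The run of benR ORFs 4 to 7 rose as well, ORF 6 by 1.18 (SE 0.28, adjusted p = 0.0014), 2.81 and 3.12, and TOL ORF 2 rose by 0.80 (SE 0.30, adjusted p = 0.023), 4.41 and 3.05. benR ORF 2, an AraC-family ORF with the coding length of the regulator gene benR but without a matching neighbour, fell (-1.68, SE 0.32, adjusted p = 0.0004, then -1.12 and -3.42).

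In this toluene comparison 4431 probes were called after loess (2416 higher, 2015 lower), 4256 after median centring (3467 and 789) and 7361 in the Agilent values (3731 and 3630). Leaving out toluene replicate 2 or 4 gave 2223 or 2346. Of the lists, 697 lower block probes were higher and 26 lower (788 and 33 adjusted over the list alone), 378 upper block probes were higher and 57 lower (414 and 68), and 281 benR tile probes of 1043 were higher and 249 lower (306 and 271). The lower block passed the list test (adjusted p = 0.00053), the upper block did not after loess (0.084) but did under the other scalings (1.6e-08 and 1.4e-06), in a fit of only these arrays (0.03) and with the block probes at weight 0 in loess (0.00079). The benR tile did after median centring (0.041) but not after loess (0.55), with a mean of -0.09 against a median of its probes of 0.18. Of the regulator probes, 42 were higher and 169 lower (47 and 170), downward as a list (adjusted p = 0.0039; -2.14; 0.3 in a fit of only these arrays) but upward after median centring (0.0063; 1.75).

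o-Xylene, an isomer of m-xylene, gave the highest upper block values of the 6 groups. All 6 upper block ORFs rose under every scaling, the block standing at 2.76 ± 2.48 (loess), 7.23 ± 0.72 (median-centred) and 6.36 ± 2.86 (Agilent). TOL ORF 34 rose by 3.26 (SE 0.53, adjusted p = 0.00018), 7.93 and 6.91, and the aldehyde dehydrogenase ORF 35 by 3.21 (SE 0.52), 7.94 and 6.68. In the lower block, at 0.66 ± 0.70, 3.46 ± 0.65 and 2.78 ± 0.41, 8 of 14 ORFs rose after loess, 13 after median centring and 14 in the Agilent values. TOL ORF 2 rose (1.12, SE 0.30, adjusted p = 0.0039, then 4.99 and 3.60), while benR ORFs 1, 2, 3 and 8 to 11 fell after loess, ORF 2 by 1.76 (SE 0.32).

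The o-xylene count was 3658 probes after loess (1934 higher, 1724 lower), 3701 after median centring (3310 and 391) and 6775 in the Agilent values (3855 and 2920), and it was 2048 or 1993 without o-xylene replicate 2 or 4. Of the upper block probes 642 were higher and 3 lower (658 and 4 adjusted over the list alone; list test adjusted p = 0.00053). In the lower block the counts were 463 higher and 70 lower (547 and 75; 0.0099, and 0.089 without the dye coefficient). Of the benR tile probes 51 were higher and 254 lower (54 and 256; 0.084, 0.034 without o-xylene replicate 3, and 0.018 in the Agilent values). Regulator probes were 55 higher and 163 lower (74 and 168; downward, 0.049), a shift that turned upward after median centring (0.00011) and did not pass without o-xylene replicate 1, 2 or 3 (0.28, 0.17 and 0.07), in a fit of only these arrays (0.39) or with only feature outliers left out (0.093).

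3MBz, the lower pathway's substrate, was set against C-runout. The lower block rose in all 14 ORFs under every scaling, at 2.25 ± 0.71 (loess), 3.73 ± 0.66 (median-centred) and 3.28 ± 0.14 (Agilent), with TOL ORF 11 at 2.74 (SE 0.29) and the Rieske ORF 16 at 2.60 (SE 0.18, adjusted p = 7.5e-10). No upper block ORF was called under any scaling, and the block stood at -0.23 ± 0.23, -0.01 ± 0.10 and -0.01 ± 0.25. On the chromosome, pcaI ORF 1 (0.92, SE 0.13), pcaR ORF 1 (0.90, SE 0.14) and rpoN ORF 2 (1.98, SE 0.25) rose. So did pcaR ORF 6 with the coding length of pcaD (0.72, SE 0.13) and catA1 ORFs 2 to 4. None of these ORFs was called against succinate. benR ORF 4 rose by 1.12 (SE 0.24, adjusted p = 0.00042), but benR ORFs 4 to 7 averaged 2.42 in replicate 4 against 0.38, 0.60 and 0.44 in replicates 1 to 3. Without 3MBz replicate 4, benR ORF 4 rose by 0.64 (SE 0.17, adjusted p = 0.004), whereas benR ORFs 5 and 6 (0.34 and 0.48) and catA1 ORFs 2 and 3 (0.18 and 0.15) did not pass.

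For 3MBz, 4540 probes were called after loess (2723 higher, 1817 lower), 3948 after median centring (3044 and 904) and 5519 in the Agilent values (2984 and 2535). Of the lower block probes 994 were higher and 6 lower (1001 and 9 adjusted over the list alone; list test adjusted p = 2e-07), of the pca tile probes 357 of 988 were higher (377 higher and 120 lower adjusted over the list alone, 0.0099, 0.071 without 3MBz replicate 2, 0.097 in a fit of only these arrays, 0.36 in the Agilent values and 0.19 in the value table). Of the catA1 tile probes 12 of 320 were lower and most called ones higher (112 higher and 14 lower adjusted over the list alone, 0.0049), but without 3MBz replicate 4 the catA1 tile, 3MBz against C-runout, stood at 0.21 and did not pass (adjusted p = 0.064). In a fit of only these arrays it did not pass either (0.17). Of the upper block probes 0 were higher by limma and 97 lower (0 and 52; 0.83), and of the benR tile probes 213 were higher and 221 lower (236 and 231; 0.24). Outside the lists, TOL-22661 of TOL ORF 24 rose by 3.95 (SE 0.41) and TOL-21321 of TOL ORF 22 by 3.79 (SE 0.37).

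Benzoate against C-runout raised ORFs of the benR, catA1 and TOL tiles. benR ORFs 4 to 7 rose, ORF 4 by 1.32 (SE 0.24, adjusted p = 0.00028), 4.35 and 3.93 and ORF 6 by 1.01 (SE 0.28), 3.71 and 3.99. In the catA1 tile, ORF 2 with the coding length and order of catC (0.82, SE 0.18, then 1.88 and 2.85) and ORF 3 (0.60, SE 0.15, then 1.59 and 2.38) rose. The gene catC encodes an enzyme of catechol degradation. The lower block of the TOL plasmid rose in 11 of 14 ORFs, at 0.95 ± 0.35, 3.69 ± 0.95 and 3.22 ± 0.18, and no upper block ORF was called higher. benR ORF 2 fell in benzoate (-2.0, SE 0.32), as in the other 5 groups, where it lay between -1.87 and -1.61 in the loess values and below 0 under each scaling.

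Benzoate calls came to 3788 after loess (1660 higher, 2128 lower), 5417 after median centring (3652 and 1765) and 6083 in the Agilent values (3150 and 2933), and to 2131, 2373 and 1810 without benzoate replicate 1, 3 or 4. Of the benR tile probes 464 were higher and 216 lower (566 and 245 adjusted over the list alone), and the list test was 0.051 after loess (0.038 without benzoate replicate 2), 2.4e-05 median-centred and 7.3e-05 Agilent. The catA1 tile (140 higher, 24 lower; 169 and 29; 0.002) and the lower block (621 and 19; 739 and 27; 0.002) passed. In a fit of only these arrays the catA1 tile did not (0.12), nor did the lower block with the block probes at weight 0 (0.072). The pca tiles, with 151 higher and 261 lower (177 and 279), had a mean of -0.34 after loess (0.82) and 0.85 after median centring (0.0063), and 0 upper block probes were higher by limma and 106 lower (0 and 97; 0.68).

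Succinate against C-runout compared cultures without a further substrate with the C-runout culture and gave the background of the substrate groups. The lower block rose at 1.20 ± 0.47 (loess), 1.96 ± 0.80 (median-centred) and 2.26 ± 0.59 (Agilent) in 13, 10 and 13 ORFs, while the upper block stood at 0.10 ± 0.14, 0.10 ± 0.10 and 0.43 ± 0.57. pcaR ORF 1 (1.30, SE 0.14), rpoN ORF 2 with the coding length and order of rapZ (1.64, SE 0.25), pcaI ORF 1 (0.83, SE 0.13) and catA1 ORF 4 (0.88, SE 0.11) rose, and benR ORFs 1 and 2 fell (-2.02 and -1.87). Of the probes, 2947 were called (1972 higher, 975 lower), with 1908 left without succinate replicate 2 and 0 by limma without background correction, where 907 had an unadjusted p under 0.05. Of the lower block probes 702 were higher and 5 lower (790 and 12 adjusted over the list alone; 0.00036). Its list test did not pass without background correction (0.42, adjusted p = 0.2) or with the block probes at weight 0 (0.1). For the pca tiles the counts were 310 higher and 87 lower (351 and 103; 0.0061). That list test did not pass in the Agilent values (0.068), without background correction (0.3) or in a fit of only these arrays (0.13). In the catA1 tile the counts were 77 higher and 2 lower (78 and 2; 0.064). Of the upper block probes 2 were higher and 8 lower (0 and 0 by limma; 0.82). TOL-21311 of TOL ORF 22 rose by 4.61 (SE 0.32) and TOL-22661 of TOL ORF 24 by 4.58 (SE 0.41).

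**Figure D2:**
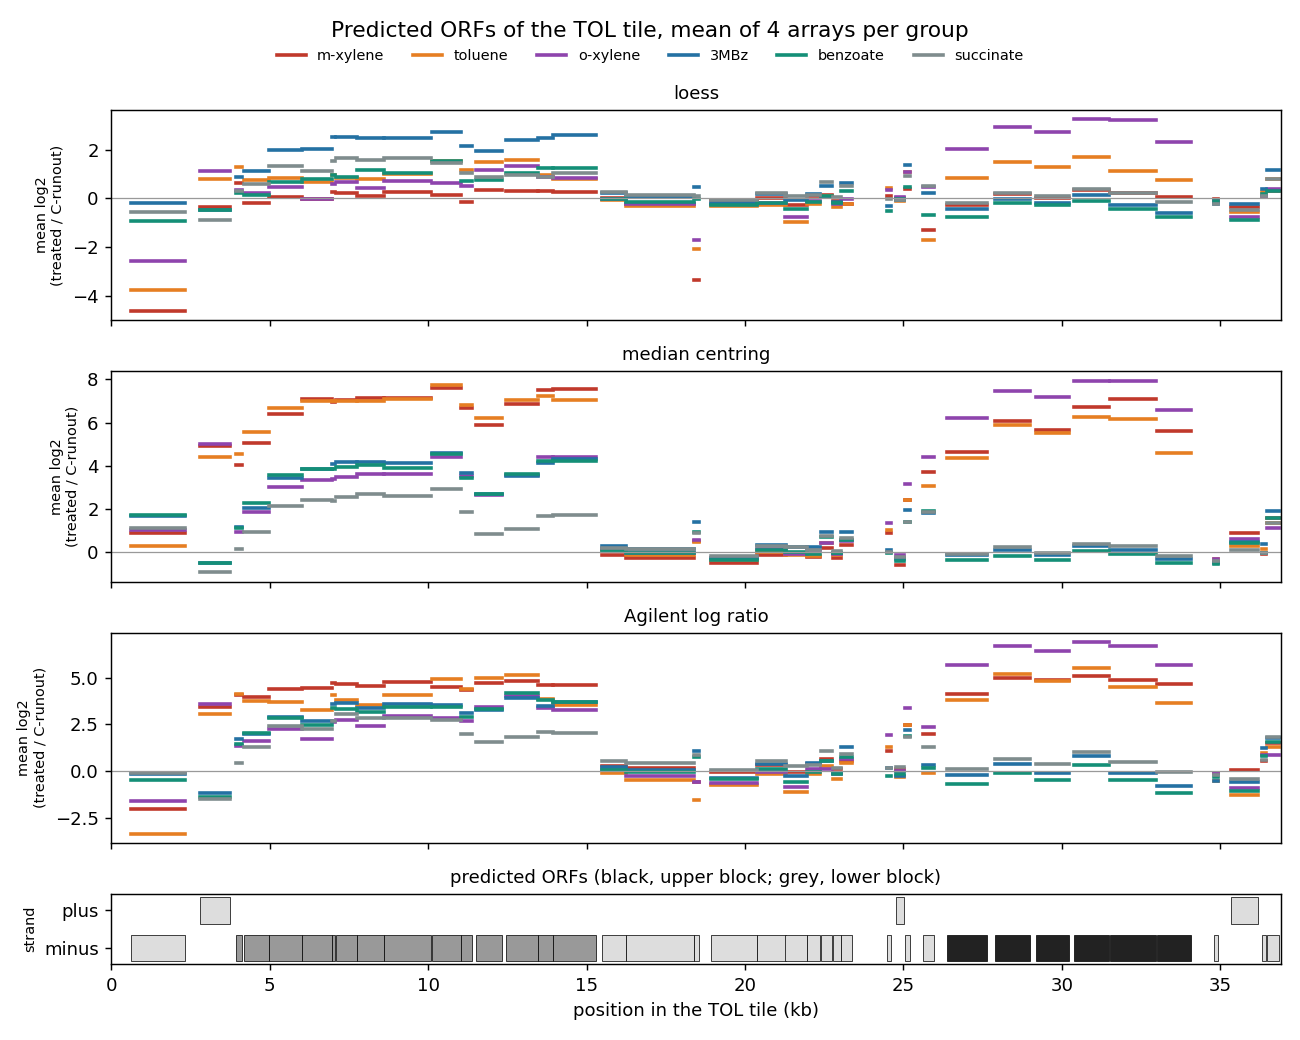
Mean log2 ratio of treated over C-runout RNA for each predicted ORF along the TOL tile (horizontal axis, kb from the start of the tile), 1 line per group (mean of 4 arrays), after loess, median centring and as the Agilent log ratio, above a map of the ORFs with the upper block, lower block and regulators. At TOL ORF 11 in the lower block the median-centred means are 7.60 in m-xylene and 7.76 in toluene against 4.58 in 3MBz, 4.56 in benzoate and 4.41 in o-xylene, whereas after loess m-xylene lies at 0.15 and 3MBz at 2.74, so that the order of the groups turns with the scaling.

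The remaining comparisons set groups against each other. m-Xylene and succinate shared a slide, 3MBz and toluene another, and o-xylene and benzoate the third, so that outside m-xylene against succinate the slide and the group cannot be told apart. m-Xylene against succinate set the substrate against cultures without it. The upper block differed by -0.01 (SE 0.69, 95% interval -1.46 to 1.43) after loess, by 5.90 median-centred and by 4.33 Agilent, with 0, 6 and 6 ORFs called higher. The lower block was lower by 1.03 after loess (SE 0.27), with 9 ORFs called lower, but higher by 4.86 and 2.30 under the other scalings, with 14 and 11 ORFs higher. Its treated net signals averaged 107581 in Cy3 and 27517 in Hyper 5 in m-xylene against 6367 and 868 in succinate, against the sign of the loess value. In TOL ORF 16 the difference was -0.76 (SE 0.26, adjusted p = 0.022), 5.82 and 2.60. TOL ORF 1 fell (-4.04, SE 0.80, adjusted p = 0.00043, then -0.21 and -1.91), and pcaR ORF 1 fell under loess (-1.03, SE 0.20) with -0.86 and -1.10 elsewhere. benR ORF 4 stood at 0.22 (SE 0.33), 2.78 and 2.47.

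Of 943 probes called in m-xylene against succinate after loess, 56 were higher and 887 lower, against 2515 and 440 of 2955 after median centring and 1602 and 218 of 1820 in the Agilent values. Of the 943, 76 were called with the same sign and 285 with the other sign after median centring. A fit of only these 8 arrays of 1 slide, listed as genes changed, m-xylene against succinate, called 1335. Within this slide the lower block, m-xylene against succinate, was lower by 1.03 after loess (adjusted p = 0.016), and the upper block, m-xylene against succinate, differed by -0.01 (adjusted p = 0.91). The count was 595 or 543 without m-xylene replicate 2 or 4 and 568 without succinate replicate 2. By list, 0 of 705 upper block probes were called by limma in either direction (0 adjusted over the list alone; list test adjusted p = 0.97; 7e-07 and 0.00017 upward under the other scalings). Of the lower block probes 0 were higher and 286 lower (0 and 499; 0.014 downward, 0.056 without m-xylene replicate 4, 0.11 without the dye coefficient; 3.4e-05 and 0.0096 upward). For the regulators the counts were 3 higher and 120 lower (5 and 141; 0.013 downward, 0.15 without background correction; 0.026 upward median-centred). In the pca tiles the counts were 1 higher and 86 lower (2 and 123; 0.011). Its list test did not pass median-centred (-0.23, adjusted p = 0.53), in the Agilent values (0.38) or without background correction (0.31).

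Toluene against succinate raised TOL ORF 2 by 1.67 (SE 0.42, adjusted p = 0.0041, then 5.34 and 4.54). benR ORF 6 rose by 1.13 (SE 0.40, adjusted p = 0.025, then 2.90 and 2.92). The upper block differed by 1.10 after loess, 5.38 median-centred and 4.15 Agilent, with 0, 6 and 6 ORFs called. The lower block differed by -0.16, 4.89 and 1.82, a direction that turned with the scaling, and 1 of its ORFs was called higher and 2 lower after loess. TOL ORF 1 (-3.19, SE 0.80), pcaG ORF 1 (-0.85, SE 0.20), pcaR ORF 2 (-1.03, SE 0.27) and pcaR ORF 1 (-0.95, SE 0.20) fell. The pcaR and pcaG values were below 0 under each scaling, but median centring called no ORF lower. After loess 957 probes were called (332 higher, 625 lower), against 2626 (2563 and 63) and 3798 (1837 and 1961) under the other scalings. The count was 219, 2323 or 312 without toluene replicate 2, 3 or 4 and 1443, 245 or 256 without succinate replicate 1, 2 or 4. Of the upper block probes 22 were higher and 0 lower by limma (0 and 0 adjusted over the list alone; 0.35, then 2.2e-06 and 0.00023). For the lower block the counts were 11 higher and 72 lower (26 and 98; 0.83, then 2.4e-05 and 0.021). In the pca tiles the counts were 3 higher and 67 lower (3 and 73; 0.022, but 0.059 without toluene replicate 4 and 0.092 or 0.078 without succinate replicate 2 or 4). This list test did not pass median-centred (0.29), without background correction (0.3) or in a fit of only these arrays (0.11). For the benR tile the counts were 54 higher and 50 lower (105 and 64; 0.19; 0.021 median-centred).

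o-Xylene against succinate asked whether the isomer raised the TOL blocks beyond their level in succinate. All 6 upper block ORFs rose under every scaling, the block by 2.66 (SE 0.69, list test adjusted p = 0.0099, but 0.064 in a fit of only these arrays), 7.13 and 5.93, and ORF 35 by 2.99 (SE 0.73, adjusted p = 0.0058). TOL ORF 2 rose by 2.00 (SE 0.42, adjusted p = 0.0036, then 5.92 and 5.10), as did TOL+2711 upstream of it (2711 to 2770, 3.63, SE 0.65). In the lower block, at -0.55 after loess (0.27), 1.5 and 0.52, 6 ORFs fell after loess, none of which was called under the other scalings, where ORFs 14 to 16 or 13 and 14 were higher. Of 1263 probes called after loess 656 were higher and 607 lower, against 1378 and 14 of 1392 and 1493 and 887 of 2380 under the other scalings. The count was 322 or 280 without o-xylene replicate 2 or 4 and 239 or 288 without succinate replicate 2 or 4. Of the upper block probes 360 were higher and 0 lower by limma (647 and 0 adjusted over the list alone). In the lower block the counts were 3 higher and 178 lower (3 and 230). For the regulators the counts were 60 higher and 1 lower (79 and 47; 0.82). In the pca tiles the counts were 7 higher and 74 lower (6 and 64; 0.03, but 0.052, 0.08 or 0.056 without o-xylene replicate 1, 2 or 4 and 0.12 or 0.11 without succinate replicate 2 or 4). Nor did their list test pass median-centred (0.62), in the Agilent values (0.27), without background correction (0.91), without the dye coefficient (0.066), in a fit of only these arrays (0.077) or with marked spots left out of the normexp fit (0.15).

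3MBz against succinate raised the lower block after loess, by 1.05 (SE 0.27, list test adjusted p = 0.012) in 10 of 14 ORFs. TOL ORF 16 rose by 1.57 (SE 0.26, adjusted p = 0.00047) and ORF 15 by 1.58 (SE 0.30, adjusted p = 0.0019). These differences kept their sign but were not called under the other scalings (block 1.77 with 0.074 and 1.02 with 0.27; ORF 16 2.61 and 1.67). For the block the list test did not pass without the dye coefficient (0.092) or with the block probes at weight 0 (0.34). benR ORF 4 rose by 1.01 (SE 0.33, adjusted p = 0.049), but without 3MBz replicate 4 it differed by 0.53 (SE 0.23) and did not pass (adjusted p = 0.18). Of the 311 probes called, 278 were higher and 33 lower, against 8 and 0 after median centring and 115 and 37 of 152 in the Agilent values. The count was 197, 113 or 120 without 3MBz replicate 1, 2 or 3 and 37, 495 or 53 without succinate replicate 2, 3 or 4. Of the lower block probes 146 were higher and 0 lower by limma (454 and 5 adjusted over the list alone). For the benR tile the counts were 18 higher and 1 lower (0.087, and 0.036 without 3MBz replicate 3). The upper block (0 higher, 1 lower, 0.75), pca tiles (mean 0, 0.93) and catA1 tile (0.09, 0.5) did not pass.

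Benzoate against succinate raised benR ORFs 4 and 5, by 1.21 (SE 0.33, adjusted p = 0.016, then 4.32 and 3.66) and 1.11 (SE 0.31, adjusted p = 0.016, then 4.12 and 3.24), and the other scalings called ORFs 4 to 11 and ORFs 4 to 10. The catA1 tile's ORF 2 stood at 0.56 (SE 0.26, adjusted p = 0.11), 1.80 and 2.25, the last 2 of which passed. pcaR ORF 1 fell (-1.24, SE 0.20, then -0.63 and -1.26) and pcaR ORF 6 fell after loess (-0.86, SE 0.19), though it stood at 0.26 after median centring. Of 482 probes called 102 were higher and 380 lower, against 1056 and 34 of 1090 and 830 and 749 of 1579 under the other scalings. The count was 87, 215, 288 or 21 without benzoate replicate 1, 2, 3 or 4 and 1057, 18 or 25 without succinate replicate 1, 2 or 4. Of the benR tile probes 33 were higher and 9 lower (198 and 37 adjusted over the list alone; 0.41, SE 0.18, list test 0.026; 2.05 and 1.72 under the other scalings). This list test did not pass without benzoate replicate 1, 3 or 4 (0.056, 0.064 and 0.07) or succinate replicate 2 or 4 (0.06 and 0.068). For the catA1 tile the counts were 14 higher and 13 lower (49 and 29; 0.34, then 0.00042 and 0.0028). In the lower block the counts were 1 higher and 24 lower (0 and 0; 0.60). For the pca tiles the counts were 3 higher and 73 lower (10 and 125; -0.57, 0.022; 0.25, 0.69 median-centred). Its list test did not pass without benzoate replicate 2 or 4 (0.071 and 0.07) or succinate replicate 2 or 4 (0.097 and 0.078), in the Agilent values (0.58), the value table (0.083), without background correction (0.54), in a fit of only these arrays (0.079) or with marked spots left out of the normexp fit (0.079).

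The isomers m-xylene and o-xylene differ in the position of 1 methyl group. After loess the upper block was lower in m-xylene by 2.67 (SE 0.69, 95% interval -4.12 to -1.23, adjusted p = 0.0099), with all 6 ORFs lower, ORF 35 by 3.00 (SE 0.73). With the treated RNA in Hyper 5 the loess values were -0.53 and -0.15 in m-xylene against 4.67 and 5.11 in o-xylene. In Cy3 they were 0.51 and 0.51 against 0.90 and 0.36. The fit holds 1 dye coefficient for all groups, so it does not model this split. Under the other scalings the upper block difference was -1.23 (-2.51 to 0.05, adjusted p = 0.16) median-centred and -1.60 (-3.12 to -0.08, adjusted p = 0.16) Agilent, with 0 ORFs called by limma. For the upper block the list test did not pass without background correction (0.18) or in a fit of only these arrays (0.12). The lower block went the other way after median centring, higher in m-xylene by 3.36 (SE 0.72, 1.85 to 4.87, adjusted p = 0.0017) in 14 ORFs, with 1.78 (0.34 to 3.22, adjusted p = 0.08) in the Agilent values and -0.49 (-1.04 to 0.07, adjusted p = 0.19) after loess. TOL ORF 2 was lower in m-xylene after loess only (-1.48, SE 0.42, adjusted p = 0.019, then -0.09 and -0.16), and benR ORF 5 was higher in the median-centred and Agilent values (0.55, SE 0.31, then 2.15 and 3.03). Of 312 probes called 38 were higher and 274 lower in m-xylene, against 1224 and 210 of 1434 and 408 and 98 of 506 under the other scalings. The count fell to 6 or 8 without m-xylene replicate 2 or 4 and to 8 or 10 without o-xylene replicate 2 or 4, was 603 or 974 without o-xylene replicate 1 or 3, and was 0 by limma in a fit of only these 8 arrays (1882 at an unadjusted p under 0.05). Of the upper block probes 0 were higher and 147 lower (0 and 631 adjusted over the list alone). In the lower block the counts were 5 higher and 0 lower (0 and 0). For the regulators the counts were 0 higher and 42 lower (0 and 128; -1.84, SE 0.53, 0.022; -0.12, 0.83 median-centred). Its list test did not pass without m-xylene replicate 4 (0.06) or o-xylene replicate 3 or 4 (0.055 and 0.056), in the Agilent values (0.63) or in a fit of only these arrays (0.071).

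m-Xylene and toluene differ by 1 methyl group, and few of their differences passed. In the upper block the difference was -1.11 (SE 0.69, 95% interval -2.55 to 0.33) after loess, 0.52 (-0.76 to 1.81) median-centred and 0.18 (-1.34 to 1.70) Agilent, and none passed (adjusted p = 0.33, 0.58 and 0.96). The lower block was lower in m-xylene by 0.87 after loess (SE 0.27, -1.43 to -0.32, adjusted p = 0.022), but not in the median-centred (-0.03, -1.54 to 1.48) or Agilent values (0.47, -0.97 to 1.91), the latter with the sign turned. After loess its list test did not pass without m-xylene replicate 2 or 4 (0.075 and 0.081) or toluene replicate 2 or 4 (0.08 and 0.065), without the dye coefficient (0.13), in a fit of only these arrays (0.099) or with the block probes at weight 0 (0.095). The 1 ORF called was TOL ORF 12 (-1.32, SE 0.32, adjusted p = 0.037, then -0.13 and -0.07). The 1 probe called was TOL-7221 (7221 to 7280) of TOL ORF 8 (-2.23, adjusted p = 0.037), which was chosen after its value was seen, and 1842 probes had an unadjusted p under 0.05. Of the lower block probes 0 were higher and 1 lower by limma (0 and 2 adjusted over the list alone). In the upper block the counts were 0 higher and 0 lower. In the Agilent values 255 probes were higher and 122 lower, and after median centring 0 were called (936 unadjusted). The count was 641 without toluene replicate 3, 25 without toluene replicate 1, 5 without m-xylene replicate 1 or 3, and 0 without toluene replicate 2 or 4 (785 and 1131 unadjusted) or m-xylene replicate 4 (836 unadjusted).

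3MBz carries 1 methyl group more than benzoate. After loess the lower block was higher in 3MBz by 1.30 (SE 0.27, 95% interval 0.74 to 1.85, adjusted p = 0.0031) in 13 ORFs, TOL ORF 16 by 1.36 (SE 0.26, adjusted p = 0.00061). The loess curve had taken 2.74 off the lower block in benzoate and 1.48 in 3MBz. The difference was 0.04 (-1.47 to 1.55) median-centred and 0.05 (-1.39 to 1.49) Agilent, neither called. For this block the list test did not pass in the value table (0.34) or with the block probes at weight 0 (0.41). In the benR tile the difference was 0.00 (-0.38 to 0.38) after loess, with a median over its probes of -0.16, and benzoate was higher in the median-centred (-1.23, SE 0.38, -2.02 to -0.44, adjusted p = 0.007) and Agilent values (-1.22, SE 0.40, adjusted p = 0.0078). In the Agilent values benR ORF 4 differed by -2.11 (SE 0.48) and catA1 ORF 2 by -1.84 (SE 0.43). In the catA1 tile the difference was 0.05 (-0.31 to 0.41) after loess, turning to -0.69 (adjusted p = 0.0063) and -0.92 (adjusted p = 0.023). Without 3MBz replicate 4 the loess differences of the benR and catA1 tiles were -0.26 and -0.17, and both passed (adjusted p = 0.00078 and 0.0078). The upper block differed by 0.20 (-1.24 to 1.64, adjusted p = 0.88), 0.22 and 0.42.

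Between these acids 470 probes were called, 457 higher in 3MBz and 13 lower, against 5 and 86 of 91 after median centring and 11 and 245 of 256 in the Agilent values. The count was 1301 without 3MBz replicate 4, 184, 5 and 67 without 3MBz replicate 1, 2 and 3, and 249, 47, 207 and 159 without benzoate replicate 1, 2, 3 and 4. Of the lower block probes 228 were higher and 0 lower by limma (703 and 0 adjusted over the list alone). For the pca tiles the counts were 50 higher and 0 lower (82 and 0; 0.57, SE 0.18, 0.18 to 0.96, 0.03; -0.07, -0.87 to 0.73, 0.85 median-centred). Its list test did not pass without 3MBz replicate 2 or 3 (0.1 and 0.081) or benzoate replicate 2 or 4 (0.091 and 0.086), in the Agilent values (1), the value table (0.4), without the dye coefficient (0.068), in a fit of only these arrays (0.054) or with marked spots left out of the normexp fit (0.065). In the benR tile the counts were 3 higher and 7 lower (2 and 3). For the catA1 tile the counts were 3 higher and 4 lower (2 and 2). pcaR ORF 6 was higher in 3MBz by 1.04 (SE 0.19, adjusted p = 0.00061) after loess but not median-centred (-0.12) or in the Agilent values (0.27).

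**Figure D3:**
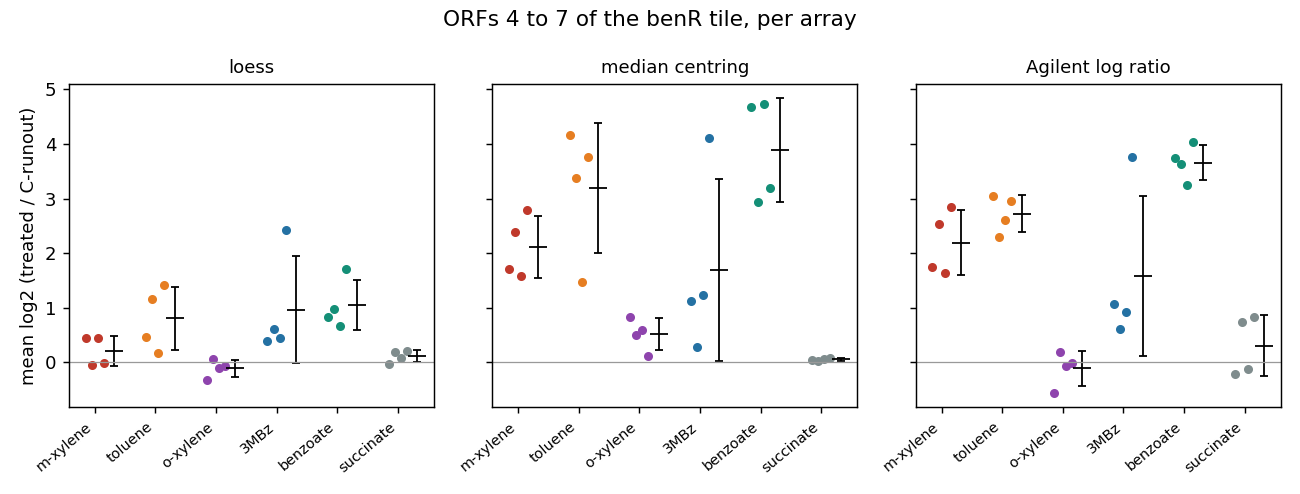
Mean log2 ratio of treated over C-runout RNA over ORFs 4 to 7 of the benR tile (vertical axis) in each array (points), with the mean and SD of the 4 arrays of each group (horizontal axis), after loess, median centring and as the Agilent log ratio. In the Agilent values the benzoate arrays lie between 3.24 and 4.03, 3MBz replicates 1 to 3 between 0.60 and 1.06 and 3MBz replicate 4 at 3.77, while in the loess values 3MBz replicate 4, at 2.42, lies above the benzoate arrays.

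The position trend along each block, as the slope of the log2 ratio per kb against that of succinate, asked whether the signal changed along a transcript. After loess over all probes none of the 10 trends passed. Along the lower block the slope was lower than in succinate by 0.094 in o-xylene, 0.098 in 3MBz and 0.083 in benzoate, each with a 2-sided exact permutation p of 0.029, the smallest that 4 against 4 arrays allow, and an adjusted p of 0.095. With only probes well above background 6 of 10 passed after loess (adjusted p = 0.048), at 0.078, 0.075 and 0.040 per kb along the upper block in toluene, 3MBz and benzoate and at -0.095, -0.098 and -0.083 along the lower block in o-xylene, 3MBz and benzoate. After median centring, a choice added later, 8 of 10 passed at an adjusted p of 0.036. These were -0.221, -0.086 and -0.108 per kb along the upper block in m-xylene, toluene and o-xylene, and -0.173, -0.123, -0.200, -0.142 and -0.130 along the lower block in m-xylene, toluene, o-xylene, 3MBz and benzoate. In the Agilent values none of the 10 passed (lowest adjusted p = 0.095). The upper block difference in toluene was 0.046 after loess and 0.039 in the Agilent values, of the other sign than after median centring. Distance was counted from the end of each block where transcription of its strand starts, so a negative slope means ratios that declined with distance from that end, relative to succinate.

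Antisense and intergenic probes, 7178 in all, were compared with succinate for m-xylene, toluene and 3MBz. In toluene 198 were called (118 higher, 80 lower; 1380 unadjusted), among them 37 probes antisense to TOL ORF 2, all higher, such as TOL-3311 (3311 to 3370, 3.15, SE 0.52, adjusted p = 0.0025). Against C-runout that probe stood at 0.07 in toluene (adjusted p = 0.92) and at -3.08 in succinate (adjusted p = 1.6e-05), where 2 of 4 arrays lay above background, and it was higher than in succinate in m-xylene (2.27) and 3MBz (2.34) as well. In m-xylene 66 were called (11 higher, 55 lower; 735 unadjusted), with 5 higher and 1 lower antisense to TOL ORF 35, and in 3MBz 47 (45 higher, 2 lower; 1008 unadjusted), 3 of them higher and antisense to TOL ORF 2. Median centring gave 344 higher and 0 lower by limma in toluene (738 unadjusted), 358 and 99 in m-xylene, and 3 and 0 in 3MBz (533 unadjusted), and the Agilent values 466 and 688, 272 and 10, and 4 and 0 (1178 unadjusted). Leaving out toluene replicate 2, 3 or 4 gave 59, 841 or 65 in toluene, and leaving out succinate replicate 2 or 4 gave 75 or 69. For m-xylene the count was 42, 40 or 43 without m-xylene replicate 1, 2 or 3 and 34 or 38 without succinate replicate 2 or 4. For 3MBz it was 25, 27 or 14 without 3MBz replicate 1, 2 or 3 and 78, 12 or 15 without succinate replicate 1, 2 or 4.

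Downstream of the lower block, on its own strand, median-centred values in successive 200-nt windows fell from 3.12 to 1.31, 0.44 and 0.05 in m-xylene and from 3.73 to 1.86, 1.09 and 0.47 in toluene, against 0.55, -0.25 and -0.65 in o-xylene and -0.22, -0.94 and -1.57 in succinate over the first 3. The loess values of the first 2 windows were 0.68 and -0.12 in m-xylene and 1.32 and 0.33 in toluene. The first window lies mostly between the lower block and TOL ORF 2, and the later ones run antisense to the 3′ end of TOL ORF 2. Differences between the groups in these windows were described, not tested. Downstream of the upper block, median-centred o-xylene values were 5.41, 5.62, 4.61, 4.34 and 4.04 over the first 5 windows, and at 600 to 800 nt 3MBz, benzoate and succinate stood at 2.41, 2.46 and 2.44.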

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

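The tests of the 3 patterns weighed here were chosen after the result was seen, whereas the counts of other splits of the samples were planned. In 3 of 48 groups of 4 arrays, a single array lay apart from the others by Dixon's criterion, where chance gives about 2.4. These were the regulators in 3MBz replicate 2 at 0.60 (gap share 0.88), the benR tile in benzoate replicate 4 at 0.36 (0.83) and the catA1 tile in 3MBz replicate 4 at 1.09 (0.942).

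Control spots for 10 genes outside the tiles, which no comparison used, gave signal above the 95th percentile of negative-control spots in the treated channel of most of the 24 arrays: fabD, recA, rpoS and trpG in 24, argF in 23, lysA and trpA in 22, proC and trpB in 21, and rpoD in 18.

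All 35 splits of the 8 arrays of a comparison, the real one among them, were fitted in the same way. Only the real split reached its count in o-xylene against succinate (1263 against a highest other of 10). The same held for m-xylene against o-xylene (312 against 10) and 3MBz against succinate (311 against 189). This is the lowest share 35 splits allow, was not adjusted over comparisons, and these groups lie on different slides. Chance and slide are therefore not excluded. A fit of only the 8 arrays called 596, 0 by limma (1882 unadjusted) and 67, in this order. Leaving out 1 replicate gave 239 to 1769, 6 to 974 and 37 to 495. Other splits gave at least as many for toluene against succinate (2 splits, 957 against 1369), benzoate against succinate (2, 482 against 754), 3MBz against benzoate (2, 470 against 529) and m-xylene against toluene (14, 1 against 453), and chance stays open there. The same holds for the antisense and intergenic calls of toluene (2, 198 against 546) and 3MBz (2, 47 against 70). For m-xylene against succinate the split by dye called 3947 probes against 943 (2 splits) and 2607 antisense and intergenic probes against 66 (2 splits), which points to a structure of the samples by dye on that slide.

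The TOL blocks, not raised after loess in m-xylene against succinate, were weighed against their raw signals. That the upper block's RNA was not raised is excluded: its same-dye excess over other sense probes, m-xylene against succinate arrays of the same slide, was at least 3.11 (log2). The same is excluded for the lower block, with an excess of at least 3.95, although the loess values put it lower in m-xylene. A candidate explanation is that the loess curve follows the raised block probes, since with the block probes at weight 0 the upper block rose by at least 1.79 in each of m-xylene, toluene and o-xylene. The remaining distance to the median-centred values, which overstated a simulated rise on m-xylene replicates 2 and 4, was not accounted for.

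3MBz replicate 4 stood high in the benR tile, at 3.77 over ORFs 4 to 7 in the Agilent values against 0.60 to 1.06 in the other 3MBz arrays. A swap with a benzoate array stays open, since the lowest benzoate array lay above the highest of the other 3MBz arrays by 2.18 in the Agilent values and 1.70 after median centring, but by only 0.07 after loess. Marked outlier spots alone are excluded: without them the array lay at least 1.81 above the other 3MBz arrays under each scaling. But it held 1387 feature outliers against 55 to 152 on those arrays, and poor quality of its unmarked spots stays open. A wrong label or a mixed sample likewise stays open: the array lay 0.56 from the same-dye 3MBz array and 0.45 from the nearest same-dye benzoate array over 62 other ORFs, but the groups lie on different slides. No biological explanation was tested.

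Signal downstream of the lower block, antisense to TOL ORF 2, was present in m-xylene and toluene. Copies of the opposite strand's transcript stay open. At 200 to 400 nt the lowest m-xylene array lay above the highest o-xylene array by 0.41 after median centring and 0.81 in the Agilent values, where the plus strand was not lower in o-xylene (4.32 against 3.85 and 2.93 against 2.71). After loess, however, the arrays overlapped (-0.22), and the groups lie on different slides. Transcription past the end of the lower block stays open too: median-centred values fell over 3 successive windows in 8 of 8 m-xylene and toluene arrays, but also in all 16 arrays of the other groups. No biological explanation of the difference between the groups was tested.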

How the results depend on the processing

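Alternatives added after the data were seen are the loess with the blocks at weight 0, the 2 other treatments of outlier-marked spots, median centring for the trends and for antisense and intergenic probes, the ORF means as a result of their own, also without 3MBz replicate 4, and a fit without the 8 arrays of the m-xylene and succinate slide. The other alternatives were planned. Of 1922 comparisons of a result with an alternative, 1483 kept their side of the threshold (92 with the other sign, past the threshold in neither fit), 94 lost and 110 gained a call in the same direction, 178 moved and 57 reversed. A further 10 exact sign-flip and 40 exact permutation tests of trends with too few arrays to pass say nothing of whether a trend passes. The dim-probe filter kept 101 of 102, the Theil-Sen slope all 10 trends, and the fit without the m-xylene and succinate slide all 5 counts it could give. Centring on the Agilent spike-in spots and the slide as a random block were planned but not run, since observed and expected spike-in values correlated at only 0 to 0.181 per the file headers, and since each slide holds whole groups. For every result listed here as changed, the cause was not tested, except for the upper block after loess (block probes at weight 0) and that a minimum fold makes calls stricter by construction.

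With the Agilent log ratio, the probes called came to 4485 in m-xylene against C-runout (3401 higher, 1084 lower), 7361 in toluene against C-runout (3731 higher, 3630 lower) and 6775 in o-xylene against C-runout (3855 higher, 2920 lower). The count was also 6083 in benzoate against C-runout (3150 higher, 2933 lower), 1820 in m-xylene against succinate (1602 higher, 218 lower) and 3798 in toluene against succinate (1837 higher, 1961 lower). Further counts were 2380 in o-xylene against succinate (1493 higher, 887 lower), 152 in 3MBz against succinate (115 higher, 37 lower) and 1579 in benzoate against succinate (830 higher, 749 lower). It called 506 in m-xylene against o-xylene (408 higher, 98 lower), 377 in m-xylene against toluene (255 higher, 122 lower) and 256 in 3MBz against benzoate (11 higher, 245 lower). Antisense and intergenic calls under the Agilent log ratio were 282 in m-xylene against succinate (272 higher, 10 lower), 1154 in toluene against succinate (466 higher, 688 lower) and 4 in 3MBz against succinate (4 higher, 0 lower by limma, 1178 unadjusted). The regulators reversed, at 0.29 in o-xylene against C-runout (adjusted p = 0.84) and 0.57 in m-xylene against succinate (adjusted p = 1). Reversed too, the upper block stood at 4.33 in m-xylene against succinate (adjusted p = 0.00017). The lower block reversed, at 2.30 in m-xylene against succinate (adjusted p = 0.0096), 1.82 in toluene against succinate (adjusted p = 0.021) and 0.47 in m-xylene against toluene (adjusted p = 0.78). Reversed too, the benR tile stood at -1.22 in 3MBz against benzoate (adjusted p = 0.0078). The catA1 tile reversed, at -0.92 in 3MBz against benzoate (adjusted p = 0.023).

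With median centring, the probes called came to 5208 in m-xylene against C-runout (3537 higher, 1671 lower), 2955 in m-xylene against succinate (2515 higher, 440 lower) and 2626 in toluene against succinate (2563 higher, 63 lower). Further counts were 8 in 3MBz against succinate (8 higher, 0 lower by limma), 1090 in benzoate against succinate (1056 higher, 34 lower) and 1434 in m-xylene against o-xylene (1224 higher, 210 lower). It called 0 in m-xylene against toluene (0 by limma, 936 unadjusted) and 91 in 3MBz against benzoate (5 higher, 86 lower). Antisense and intergenic calls under median centring were 457 in m-xylene against succinate (358 higher, 99 lower), 344 in toluene against succinate (344 higher, 0 lower by limma) and 3 in 3MBz against succinate (3 higher, 0 lower by limma, 533 unadjusted). The regulators reversed, at 2.34 in m-xylene against C-runout (adjusted p = 0.00032), 1.75 in toluene against C-runout (adjusted p = 0.0063), 2.46 in o-xylene against C-runout (adjusted p = 0.00011), 1.97 in m-xylene against succinate (adjusted p = 0.026) and 2.10 in o-xylene against succinate (adjusted p = 0.014). Reversed too, the benR tile stood at 1.02 in toluene against C-runout (adjusted p = 0.041) and -1.23 in 3MBz against benzoate (adjusted p = 0.007). The pca tiles reversed, at 0.85 in benzoate against C-runout (adjusted p = 0.0063), 0.25 in benzoate against succinate (adjusted p = 0.69) and -0.07 in 3MBz against benzoate (adjusted p = 0.85). Reversed too, the upper block stood at 5.90 in m-xylene against succinate (adjusted p = 7e-07). The lower block reversed, at 4.86 in m-xylene against succinate (adjusted p = 3.4e-05), 4.89 in toluene against succinate (adjusted p = 2.4e-05) and 3.36 in m-xylene against o-xylene (adjusted p = 0.0017). Reversed too, the catA1 tile stood at -0.69 in 3MBz against benzoate (adjusted p = 0.0063). Position trends passing at an adjusted p of 0.036, one of them (upper block, toluene) reversed, were -0.221 in m-xylene, -0.086 in toluene and -0.108 in o-xylene along the upper block and -0.173 in m-xylene, -0.123 in toluene, -0.2 in o-xylene, -0.142 in 3MBz and -0.13 in benzoate along the lower block.

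With the value table of the authors, the probes called came to 6271 in m-xylene against C-runout, 5587 in o-xylene against C-runout and 6142 in benzoate against C-runout. It called 3961 in m-xylene against succinate, 4679 in toluene against succinate and 3188 in o-xylene against succinate. Calls also numbered 1048 in 3MBz against succinate, 1961 in benzoate against succinate and 1936 in m-xylene against o-xylene. The count was also 254 in m-xylene against toluene and 111 in 3MBz against benzoate. 49 of 84 list tests passed there, against 27. The upper block reversed, at 3.26 in m-xylene against succinate (adjusted p = 6.9e-08). Reversed too, the lower block stood at 2.28 in m-xylene against succinate (adjusted p = 1.6e-05), 2.17 in toluene against succinate (adjusted p = 8.6e-06), 0.84 in benzoate against succinate (adjusted p = 0.048), 1.91 in m-xylene against o-xylene (adjusted p = 0.00033) and 0.11 in m-xylene against toluene (adjusted p = 0.79). The regulators reversed, at 0.08 in o-xylene against succinate (adjusted p = 0.0053). Reversed too, the benR tile stood at -0.70 in 3MBz against benzoate (adjusted p = 0.0074). The catA1 tile reversed, at -0.35 in 3MBz against benzoate (adjusted p = 0.0066).

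With no background correction, the probes called came to 6344 in o-xylene against C-runout, 5798 in benzoate against C-runout and 0 in succinate against C-runout (0 by limma, 907 unadjusted). Calls also numbered 1 in m-xylene against succinate (0 higher, 1 lower by limma, 607 unadjusted), 3482 in toluene against succinate and 3484 in o-xylene against succinate. The count was also 3058 in 3MBz against succinate, 2636 in benzoate against succinate and 1801 in m-xylene against o-xylene. Further counts were 2572 in m-xylene against toluene and 1375 in 3MBz against benzoate. Reversed lists were the lower block at 0.23 in m-xylene against succinate (adjusted p = 0.5) and 0.12 in m-xylene against toluene (adjusted p = 0.96) and the regulators at 0.60 in m-xylene against o-xylene (adjusted p = 0.38) and 1.48 in m-xylene against toluene (adjusted p = 0.035). With no dye coefficient, the probes called came to 561 in m-xylene against succinate, 736 in o-xylene against succinate and 71 in 3MBz against succinate. The count was also 178 in benzoate against succinate, 93 in m-xylene against o-xylene and 2 in 3MBz against benzoate (2 higher, 0 lower by limma, 1852 unadjusted).

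With only the arrays of the groups compared, the probes called came to 3220 in m-xylene against C-runout, 2323 in toluene against C-runout and 82 in toluene against succinate. Further counts were 596 in o-xylene against succinate, 67 in 3MBz against succinate and 1570 in benzoate against succinate. It called 0 in m-xylene against o-xylene (0 by limma, 1882 unadjusted) and 0 in m-xylene against toluene (0 by limma, 1174 unadjusted). With a further minimum of 2-fold, the probes called came to 2496 in benzoate against C-runout and 1932 in succinate against C-runout.

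Both signs of the 4 GenePix columns of m-xylene were run. As deposited they go against the raw signals of the upper block. With the GenePix columns as deposited, the probes called came to 5070 in m-xylene against C-runout, 4403 in m-xylene against succinate and 6000 in m-xylene against o-xylene. Calls also numbered 7214 in m-xylene against toluene. The upper block reversed, at -2.52 in m-xylene against C-runout (adjusted p = 1.2e-06). Reversed too, the lower block stood at -1.59 in m-xylene against C-runout (adjusted p = 2e-05). The regulators reversed, at 1.17 in m-xylene against C-runout (adjusted p = 1.3e-10), 1.69 in m-xylene against succinate (adjusted p = 7e-10), 1.61 in m-xylene against o-xylene (adjusted p = 6.3e-11) and 2.31 in m-xylene against toluene (adjusted p = 3.4e-12). Reversed too, the catA1 tile stood at 0.32 in m-xylene against C-runout (adjusted p = 0.011). The pca tiles reversed, at 0.87 in m-xylene against C-runout (adjusted p = 7.1e-06), 0.61 in m-xylene against succinate (adjusted p = 0.022) and 1.36 in m-xylene against o-xylene (adjusted p = 9.9e-06). With the GenePix columns with their sign turned, the probes called came to 5060 in m-xylene against C-runout, 4638 in m-xylene against succinate and 4170 in m-xylene against o-xylene. The count was also 4010 in m-xylene against toluene. The upper block reversed, at 2.45 in m-xylene against succinate (adjusted p = 5.8e-05). Reversed too, the lower block stood at 0.18 in m-xylene against succinate (adjusted p = 0.42). The benR tile reversed, at 0.54 in m-xylene against succinate (adjusted p = 0.03).

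With loess with the 2 TOL blocks at weight 0, the probes called came to 2041 in m-xylene against C-runout, 1911 in toluene against succinate and 53 in 3MBz against succinate. Further counts were 1395 in benzoate against succinate, 1068 in m-xylene against o-xylene and 170 in m-xylene against toluene. The regulators reversed, at 0.64 in toluene against C-runout (adjusted p = 0.85) and 1.28 in o-xylene against C-runout (adjusted p = 0.13). Reversed too, the pca tiles stood at 0.14 in o-xylene against C-runout (adjusted p = 0.019). The lower block reversed, at 0.65 in m-xylene against succinate (adjusted p = 0.7) and 2.88 in toluene against succinate (adjusted p = 0.03). With outlier-marked spots also left out of the normexp fit, the probes called came to 2254 in toluene against succinate, 2304 in o-xylene against succinate and 578 in 3MBz against succinate. It called 1315 in benzoate against succinate, 1037 in m-xylene against o-xylene and 523 in m-xylene against toluene. With only the spots marked as feature outliers left out, the probes called came to 0 in m-xylene against toluene (0 by limma, 1892 unadjusted).

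With only probes well above background, 6 position trends passed at an adjusted p of 0.048: 0.078 in toluene, 0.075 in 3MBz and 0.04 in benzoate along the upper block and -0.095 in o-xylene, -0.098 in 3MBz and -0.083 in benzoate along the lower block.

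A replicate block in place of the dye coefficient called 34 in m-xylene against o-xylene (9 higher, 25 lower) and 0 in m-xylene against toluene (0 by limma, 1750 unadjusted) and 26 in 3MBz against succinate (25 higher, 1 lower) among antisense and intergenic probes. It changed no other call among the 99 other comparisons. The numbers pair no samples in the labels: of 60 pairs of arrays with the same number, 33 correlated over 0.1 (from -0.39 to 0.62), 15 of 24 arrays lay closest to their own number, and with the dye effect removed 17 of 60 and 0 of 24 did.

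Leaving out each replicate in turn gave counts of 516 to 851 in m-xylene against C-runout, 543 to 1206 in m-xylene against succinate, 6 to 974 in m-xylene against o-xylene, 0 to 641 in m-xylene against toluene and 1993 to 3814 in o-xylene against C-runout. The ranges were 239 to 1769 in o-xylene against succinate, 3303 to 4494 in 3MBz against C-runout, 37 to 495 in 3MBz against succinate, 5 to 1301 in 3MBz against benzoate and 2223 to 5047 in toluene against C-runout. They were 219 to 2323 in toluene against succinate, 1810 to 3944 in benzoate against C-runout, 18 to 1057 in benzoate against succinate and 1908 to 3004 in succinate against C-runout. Antisense and intergenic counts ranged from 34 to 78 in m-xylene against succinate, 12 to 78 in 3MBz against succinate and 59 to 841 in toluene against succinate. List tests passing ranged from 22 to 38 of 84. Slopes minus that of succinate (upper, then lower block) ran from -0.043 to -0.007 and -0.068 to -0.018 in m-xylene. They ran from 0.024 to 0.07 and -0.084 to -0.037 in toluene and from -0.068 to -0.05 and -0.118 to -0.066 in o-xylene. They ran from 0.033 to 0.051 and -0.119 to -0.086 in 3MBz and from 0.02 to 0.047 and -0.097 to -0.071 in benzoate. Without 3MBz replicate 4 the difference between 3MBz and benzoate reversed in the benR tile (-0.26, adjusted p = 0.00078) and the catA1 tile (-0.17, adjusted p = 0.0078; at most 0.15 without another one).

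List tests lost their call: with the Agilent log ratio they were regulators (m-xylene against C-runout, m-xylene against o-xylene), pca tiles (3MBz and succinate against C-runout, m-xylene, o-xylene and benzoate against succinate, 3MBz against benzoate), lower block (3MBz against succinate, 3MBz against benzoate) and upper block (m-xylene against o-xylene). With no background correction they were lower block (succinate against C-runout), pca tiles (succinate against C-runout, m-xylene, toluene, o-xylene and benzoate against succinate), regulators (m-xylene against succinate) and upper block (m-xylene against o-xylene). Under median centring they were pca tiles (m-xylene, toluene and o-xylene against succinate), lower block (3MBz against succinate, m-xylene against toluene, 3MBz against benzoate), upper block (m-xylene against o-xylene) and regulators (m-xylene against o-xylene). With the value table they were pca tiles (3MBz against C-runout, benzoate against succinate, 3MBz against benzoate) and lower block (3MBz against benzoate). With no dye coefficient they were lower block (o-xylene against C-runout, m-xylene and 3MBz against succinate, m-xylene against toluene) and pca tiles (o-xylene against succinate, 3MBz against benzoate). With only the groups compared they were regulators (toluene and o-xylene against C-runout, m-xylene against o-xylene), catA1 tile (3MBz and benzoate against C-runout), pca tiles (3MBz and succinate against C-runout, toluene, o-xylene and benzoate against succinate, 3MBz against benzoate), upper block (o-xylene against succinate, m-xylene against o-xylene) and lower block (m-xylene against toluene). With the 2 TOL blocks at weight 0 they were lower block (benzoate and succinate against C-runout, 3MBz against succinate, m-xylene against toluene, 3MBz against benzoate). With marked spots left out of the normexp fit they were pca tiles (o-xylene and benzoate against succinate, 3MBz against benzoate). With only the feature outliers left out they were regulators (o-xylene against C-runout).

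Signal limits the low end. On the m-xylene and succinate slide the Cy3 background was high, and as few as 750 of 14704 spots were well above it in the C-runout channel, so ratios there rest on the background correction.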

Other observations

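Among the control spots, recA stood at 1.53 ± 0.61 after loess in 3MBz, 1.86 ± 0.35 median-centred and 2.08 ± 0.84 in the Agilent values (n = 4), and fabD in succinate at 1.98 ± 0.22, 3.66 and 3.52. For rpoS in m-xylene the sign turned with the scaling (-6.66, 3.04 and -0.95). These values were not tested.

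The ORF means were added as results of their own after the data were seen. They called 14 of 77 ORFs in m-xylene against C-runout after loess, 49 after median centring and 41 in the Agilent values, and 11 ORFs in 3MBz against succinate after loess against 0 by limma under the other scalings.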
